A study of Homo sapiens with 12 samples.

How the data were processed

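Total RNA of MCF-7 cells was labelled with biotin by in vitro transcription and hybridised to single-colour Affymetrix arrays, per the labels' protocols, and the platform annotation given with the table is that of the Human Genome U133 array A. The deposited table holds 22215 probe sets on 12 arrays with no missing value. Per the submitters' processing notes its values were made with RMA, whose version is not stated; the background correction, normalization and annotation settings are not given in the sources used here. The values were taken as deposited log2 values: the labels do not name the base, but the highest value, 13.1, corresponds to 8689 on a log2 scale and to 481690 on a natural log scale, and a 16-bit scanner reaches 65535. Control probe sets were not in the table used here, so RNA quality could not be read from probe sets along the housekeeping transcripts.

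Groups and replicate numbers came from the sample titles and the dose and time from the series' design text, which gives no vehicle or time for the control. The annotation gave 1 gene for 19065 probe sets, several for 1043 and none for 2107. Of the probe sets with 1 gene, 19053 matched a current symbol in the RefSeq gene table of the assembly GRCh38.p14, and 0 symbols needed an update. Probe sets with several genes or none stayed out of the gene tests. A gene was represented by its probe set with the highest mean over all arrays, which left 11963 genes. Other probe sets were compared in a fit of all probe sets with 1 gene, leaving out genes named only as list members. In that fit 28 named calls had other probe sets. All of these had the same sign in 24, and at least 1 was called the same way in 10. None was called the opposite way, so 18 of the 28 rest on the brightest probe set alone. ID2 and CBX6 for estradiol against control were not called in that fit and are not among the 28.

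Limma (3.58.1, in R 4.3.3) was fitted to the 12 arrays with a mean for each of the 4 groups, which share 1 estimate of the spread with 8 residual degrees of freedom, and empirical Bayes moderation added 2.03. Contrasts gave each agent and the combination against control, the combination against each agent, and the interaction, the combination minus both single treatments plus control. P-values were two-sided and adjusted by the Benjamini-Hochberg method over genes within each contrast, and an adjusted p under 0.05 was a call. No intensity filter or added constant was used. Errors after ± are SE of limma's contrast unless named as SD. Every choice of test, gene list and named gene was fixed before the data were examined, apart from those the text names as chosen later. Named genes were the 10 largest rises and the 10 largest falls among calls with separated arrays, up to 4 members of smallest p in each list discussed, the 10 genes of smallest p where the interaction called fewer than 10, and 10 genes named in advance, of which BIRC3 had no probe set named in the annotation used here. Complete separation of 3 arrays from 3 is reached by chance in 10% of genes.

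The 28 gene lists covered estrogen response, NF-kB and inflammatory genes, cell cycle, stress pathways, other signalling and markers of luminal and other cell types, and the results give each list's test. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with the adjustment over the lists of a contrast, and again with the correlation estimated from the residuals. Counts "adjusted over the list alone" apply the adjustment to the list's members only. Simulations of unchanged groups gave the arrays' residuals a random order and random signs, 100 times. The background bound was set after the values were seen. The array span was the SD of log2 values over the 11963 genes, and plots were drawn with matplotlib 3.10.9.

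The fit was tested on simulated data in which 200 of the 11963 genes were changed. With independent noise it recovered 94.6% of changes of 0.5 and 98.7% of changes of 1 on the log2 scale for estradiol against control, and 90.5% and 97.5% for the interaction, with 4.75% and 5.07% false calls. The changed genes were drawn from all genes, of which 18.9% lay above the background bound. For estradiol against control the median SE was 0.07 above that bound and 0.03 over all genes. So many changed genes also ease the adjusted threshold. These shares are therefore no measure of power for brighter genes in the real fit, where a TFF1 interaction of 3.01 was not called (limma's adjusted p = 0.245). When the noise kept the arrays' shared axis of variation, false calls made up 39.4% for estradiol against control, 19.5% for both against control and 28.7% for the interaction.

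Alternatives were quantile normalization, median scaling, a filter on dim genes, the mean of all probe sets of a gene, every probe set tested alone, fits to 2 groups only, a variance trend with robust moderation, array weights, the replicate number as a block and leaving out each array in turn. After the data were seen, the array span as a covariate, genes above background only, and a fit without the 2 narrowest arrays, which leaves 1 estradiol array, were added. A choice of added constant planned for linear values was not needed for log2 values.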

Results

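Gene expression was measured in MCF-7 cells, a human breast cancer line that grows in response to estrogen through estrogen receptor alpha. The line was studied as a control, with estradiol at 10 nM, with tumour necrosis factor alpha (TNFa) at 10 ng/ml, or with both agents together, and the treatments lasted 2 h. Estradiol is the main ligand of the receptor, and TNFa is an inflammatory cytokine that acts through the transcription factor NF-kB. Each of the 4 groups had 3 arrays, 12 in all. The series addresses the crosstalk of the 2 signals. Nothing in the sources used here says that the 3 arrays of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

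The table held 22215 probe sets on the log2 scale, from which 11963 genes were tested. Array medians ran from 4.66 to 4.68 and the 99th percentiles from 9.26 to 9.72. Pairs of arrays within a group correlated across probe sets with r between 0.975 and 0.998, and no pair was identical. Pairs from different groups had r between 0.970 and 0.994, so the 2 ranges largely overlapped. As a measure of background, the highest group mean among 19 leukocyte and endothelial marker genes was 4.97. Averaged over the 12 arrays, 2259 genes (18.9%) lay above that bound. Values near it are compressed, so a fold against a group below the bound is given as "at least", and no fold is given where both groups lie below it. All 10 measured luminal epithelial markers were above the bound, against 0 of 6 basal epithelial markers and 1 of 11 fibroblast markers. The number of arrays limits the precision, and the median standard error (SE) of a log2 difference between groups was 0.03 over all genes and 0.07 over genes above the bound. The arrays also differed in signal span, the standard deviation (SD) of an array's log2 values over genes. The span averaged 0.76 ± 0.03 (SD, n = 3) in control, 0.72 ± 0.05 with estradiol, 0.74 ± 0.02 with TNFa and 0.75 ± 0.03 with both. The narrowest arrays were estradiol replicate 2 at 0.68 and estradiol replicate 1 at 0.70.

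**Figure D1:**
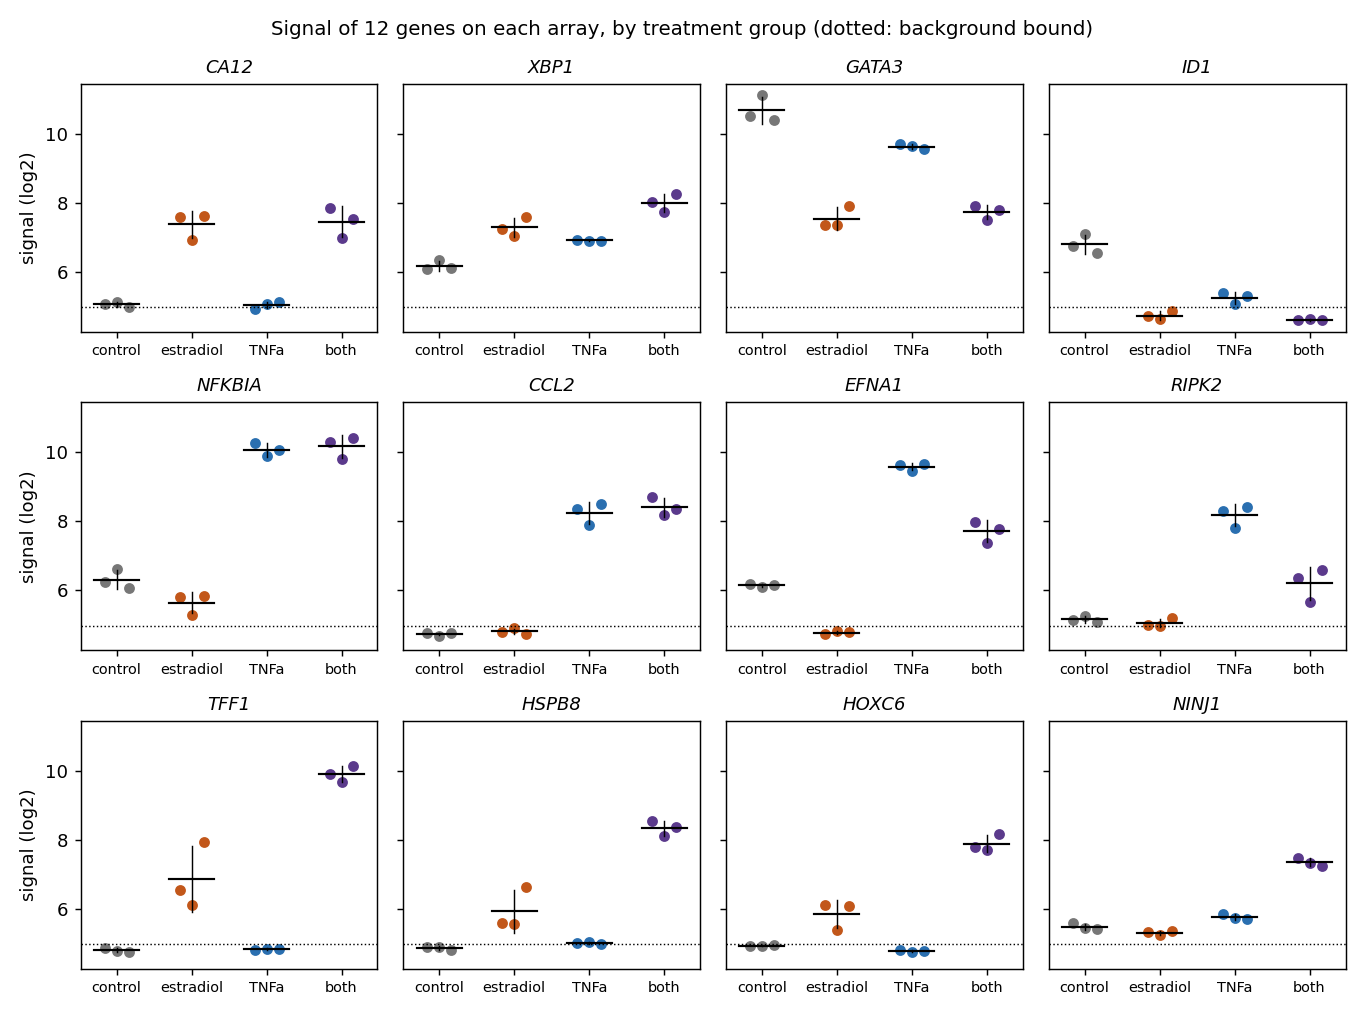
Log2 signal of 12 genes on each of the 12 arrays, by treatment group, with the group mean as a bar, the SD as a line (n = 3) and the background bound as a dotted line. TFF1 averaged 9.90 with both agents, 6.86 with estradiol and 4.82 with TNFa, whereas EFNA1 averaged 4.77 with estradiol and 9.59 with TNFa.

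Estradiol alone raised a small set of genes known to respond to the receptor and lowered others, among them GATA3 and the ID genes. CA12, a carbonic anhydrase, rose by 2.32 ± 0.22 on the log2 scale (SE, n = 3) at its brightest probe set. Its other 5 had 0.06 to 1.82, with 1 of them called. XBP1, a transcription factor that acts in the unfolded protein response, rose 2.17-fold, and the scaffold protein gene NHERF1 rose 2.03-fold. GATA3, a luminal transcription factor, fell, at -3.15 ± 0.20 (SE, n = 3), or 8.86-fold lower at its brightest probe set, from a control mean of 10.7. The size depends on the probe set, since its 2 dimmer ones, which average below the background bound, had -0.35 and -0.38 without a call, and the mean over all 3 had -1.29. The inhibitors of DNA binding ID1, ID2 and ID3 fell, with changes of -2.08, -2.18 and -0.75, and in each the estradiol mean lay below the background bound.

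This comparison asked which transcripts estradiol changed by itself within 2 h. Limma called 27 genes at the Benjamini-Hochberg threshold, 9 higher and 18 lower, and the arrays of the groups were fully separated for each. The other rises were BLVRB at 1.02, P2RY2 at 0.59, HOXC4 at 0.47, GADD45B at 0.39, WFS1 at 0.23 and STX11 at 0.10. STX11 lay below the background bound in both groups. Further falls were those of ADIPOR2, an adiponectin receptor, by 1.52, EFNA1, an ephrin ligand, by 1.37, and TNFRSF12A, a receptor of the TNF receptor superfamily, by 0.92. CBX6 fell by 0.70, ABCC5 by 0.68 and ZDHHC7 by 0.63. TFF1, a classic estrogen-induced secreted peptide, was 2.07 ± 0.36 higher (SE, n = 3) with limma's adjusted p = 0.068, and its estradiol mean was 6.86. ESR1, which encodes the receptor, was at 6.05 with estradiol and 7.21 in control, a difference of -1.16 ± 0.36 with adjusted p = 0.291. PGR and GREB1, 2 other estrogen targets, were measured below the background bound in every group, with differences of 0.07 and 0.05.

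The list of estradiol-induced genes stood apart in the camera test (adjusted p = 1.01e-16, and adjusted p = 0.011 with an estimated correlation). Among its 50 measured members 4 rose over all genes tested and 14 rose adjusted over the list alone, and 49 had a positive difference. CA12, XBP1, NHERF1 and P2RY2 were the 4. The list of estradiol-lowered genes fell (adjusted p = 2.09e-06, and 0.011 with an estimated correlation), with 2 of 20 members lower over all genes, EFNA1 and CCNG2, and 8 adjusted over the list alone. Genes of Notch, TGF-beta and BMP signalling were called lower (adjusted p = 0.0349), through ID1, ID2 and ID3 among 22 members and 5 adjusted over the list alone. Their mean was -0.27 but their median 0.01, and adjusted p = 0.147 with an estimated correlation. G2/M genes were called lower as a list (adjusted p = 1.22e-05), with 0 of 21 members passing limma's test alone and 5 adjusted over the list alone, while adjusted p = 0.176 with an estimated correlation. Among genes above the background bound, which held 4 of the 21, camera lost this call (adjusted p = 0.365). Ribosome biogenesis genes were called higher with 0 of 15 members passing over all genes and 2 adjusted over the list alone (adjusted p = 0.0185, and adjusted p = 0.464 with an estimated correlation). The p53 target genes and the cell cycle inhibitors were called lower (adjusted p = 0.0349 and 0.0356), with 0 of 14 and 1 of 14 members lower over all genes. Adjusted over the list alone, the lower members were 2 and 3, and with an estimated correlation the adjusted p was 0.147 and 0.176. GATA3 and FOXA1, 2 cofactors of the receptor, fell while XBP1 rose, and the list of the receptor and its cofactors was not called.

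The calls of ID1, GATA3, CA12, BLVRB and GADD45B were kept in 22 of 23 alternatives and that of EFNA1 in all, whereas those of ID2, CBX6, ABCC5, ADIPOR2, TNFRSF12A, P2RY2, WFS1, STX11 and CCNG2 were kept in 12 or fewer. The count rested on the arrays used: it was 12, 16 and 87 without control replicate 1, 2 or 3, 9 and 304 without estradiol replicate 1 or 3, and 17 without TNFa replicate 1, 2 or 3 or combined-treatment replicate 1. With the array span as a covariate 171 genes were called, 125 higher and 46 lower, including all 27, against 2327 genes, 951 higher and 1376 lower, with array weights and 1 gene with the arrays of these groups alone.

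TNFa alone raised genes of the NF-kB response within 2 h. NFKBIA, which encodes the NF-kB inhibitor IkB alpha, rose 13.7-fold, by 3.78 ± 0.21 on the log2 scale (SE, n = 3). The monocyte chemokine CCL2 rose at least 9.71-fold, by 3.52 ± 0.16, from a control level below the background bound. EFNA1 rose by 3.45 ± 0.13, and the early response gene IER3 and the kinase gene RIPK2 rose 8.24-fold and 8.14-fold. A second, dim probe set of RIPK2 differed by 0.06, without a call. ID1 fell 2.94-fold, by 1.56 ± 0.13.

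This comparison asked what the cytokine did in the absence of added estrogen. Limma called 21 genes, 16 higher and 5 lower, all with separated arrays. ATP1B1, a subunit of the sodium pump, rose by 1.84, the vitamin transporter gene SLC5A6 by 0.72 and the NF-kB feedback inhibitor TNFAIP3 by 0.65. SERPINA3 rose by 0.51 and the adhesion molecule ICAM1 by 0.42. Besides ID1, the falls were those of ABCC5 by 0.68, the BCL2-family death gene BIK by 0.41, FOXA1 by 0.31 and FBN2 by 0.30. Another probe set of FBN2 had the opposite sign, without a call. TFF1, ESR1, PGR and GREB1 differed from control by 0.03, -0.07, 0.04 and 0.01, each with adjusted p of 0.996 or more. No probe set was named as BIRC3 in the annotation used here.

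The list of NF-kB subunits and feedback inhibitors rose (camera adjusted p = 1.1e-13, and 0.00112 with an estimated correlation). Of its 16 measured members 4 rose over all genes, NFKBIA, TNFAIP3, NFKB1 and NFKB2, and 6 adjusted over the list alone. Immediate-early genes were called higher (adjusted p = 0.00104, and 0.0463 with an estimated correlation) with 2 of 33 members, IER3 and EGR1, and 2 higher and 1 lower adjusted over the list alone, and lost its call among genes above the background bound (adjusted p = 0.0676). Chemokines and cytokines were called higher with CCL2 and TNF among 31 members and 4 adjusted over the list alone (adjusted p = 2.64e-07, and adjusted p = 0.207 with an estimated correlation). Adhesion and surface receptor genes were called higher with ICAM1 and IFNGR2 among 23 members and 3 adjusted over the list alone (adjusted p = 0.00104, and adjusted p = 0.207 with an estimated correlation). G2/M and G1/S genes were called lower (adjusted p = 2.31e-05 and 0.0262), with 0 of 21 and 0 of 26 members passing over all genes, and 1 and 0 adjusted over the list alone. With an estimated correlation these gave adjusted p = 0.207 and adjusted p = 0.329. Among genes above the background bound camera lost both calls, with adjusted p = 0.988 for G2/M genes. The G1/S call was kept in 15 of 22 alternatives.

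The count was 11, 12 and 34 without control replicate 1, 2 or 3, and 10 and 13 without TNFa replicate 1 or 3. The excess of rises turned into one of falls without control replicate 3, with 12 higher and 22 lower, and with array weights, with 79 higher and 404 lower. In 4 of the 21 genes, NFKB2, TNF, EGR1 and FBN2, both groups lay below the background bound, with log2 differences of up to 0.30 in size.

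With both agents, genes of the 2 single responses changed, and many genes were called that neither single agent had called. TFF1 rose at least 30.5-fold, by 5.11 ± 0.36 on the log2 scale (SE, n = 3), NFKBIA 14.7-fold and CCL2 at least 10.9-fold. HSPB8, which encodes a small heat shock protein, rose at least 10.3-fold, and the homeobox gene HOXC6 at least 7.57-fold. B4GALT1, a galactosyltransferase, and IL17RB, a cytokine receptor, rose by 2.23 and 1.95, although the other 3 probe sets of B4GALT1, all dim, had at most 0.09. GATA3 fell 7.78-fold, a change of -2.96 ± 0.20, and ID1 and ID2 fell, with changes of -2.20 and -2.15, to levels below the background bound.

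This comparison asked for the whole response to the combination. Limma called 99 genes, 65 higher and 34 lower, all with separated arrays. Of the 65 higher genes, 6 were also called higher with estradiol alone, 11 with TNFa alone, and 48 with neither. Of the 34 lower genes, 11 were also called lower with estradiol alone, 5 with each agent alone, and 18 with neither. Here "neither" means only that no single comparison passed its threshold, and does not mark genes that need both agents. PIK3R3, called with neither, averaged 5.77 in control, 4.57 with estradiol, 4.79 with TNFa and 4.54 with both. TFF1, also called with neither, averaged 4.79, 6.86, 4.82 and 9.90 in the same order. Further rises were CA12 by 2.40, IER3 by 2.00 and NINJ1, a membrane protein gene of nerve injury and cell rupture, by 1.87. Falls included ADIPOR2 by 1.51, PIK3R3, a regulatory subunit of PI3 kinase, by 1.23, TSC22D3, a glucocorticoid-induced gene, by 1.00, ID3 and ABCC5 each by 0.79, CBX6 by 0.63 and ZDHHC7 by 0.61. ESR1 differed by -1.17 ± 0.36 with limma's adjusted p = 0.281.

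Estradiol-induced genes rose as a list (camera adjusted p = 1.7e-23, and 0.00393 with an estimated correlation), with 11 of 50 higher over all genes and 22 adjusted over the list alone, among them TFF1, HSPB8, XBP1 and CA12. NF-kB subunits and feedback inhibitors rose (adjusted p = 1.85e-08, and 0.00393 with an estimated correlation), with 6 of 16 higher, including NFKBIA, TNFAIP3, NFKBIE and NFKB1, and 7 higher and 1 lower adjusted over the list alone. Immediate-early genes were called higher (adjusted p = 3.62e-05, and 0.00831 with an estimated correlation). EGR1, IER3 and JUND rose and DUSP2 fell in that list, where 4 of 33 members were higher over all genes, and 11 were higher and 3 lower adjusted over the list alone. Ribosome biogenesis genes rose (adjusted p = 2.88e-09, and 0.0406 with an estimated correlation), with a positive difference in all 15 members, NOP2 and NOP16 higher over all genes and 8 adjusted over the list alone. G2/M genes fell (adjusted p = 1.42e-09, and 0.0397 with an estimated correlation), with a negative difference in all 21 members, AURKA lower over all genes and 5 adjusted over the list alone. Only 4 of the 21 were above the background bound, and among genes above it the call was lost (adjusted p = 0.082). Estradiol-lowered genes were called lower (adjusted p = 0.00034, and 0.0156 with an estimated correlation), with IRX5 and CCNG2 lower among 20 members, and 7 lower and 2 higher adjusted over the list alone. EFNA1 of that list rose by 1.58. Among genes above the background bound the call was lost (adjusted p = 0.682), and over the alternatives the mean ran from -0.06 to 0.06. A list of 4 genes studied before for this crosstalk was called higher (adjusted p = 6.03e-07, and 0.00625 with an estimated correlation), with ABCG2 and PTGES higher by 0.31 and 0.50 among 3 measured members and 3 adjusted over the list alone. PHLDA1 differed by 0.25 (adjusted p = 0.381) at its brightest probe set, while 3 of its 4 dimmer probe sets were called higher, by 0.49, 0.38 and 0.17, in a test of all probe sets. That list may have been chosen on these samples and is not independent evidence of its direction.

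Chemokines and cytokines were called higher with 5 of 31 members over all genes and 5 adjusted over the list alone (adjusted p = 2.03e-06, and adjusted p = 0.136 with an estimated correlation), including CXCL8, or interleukin 8, by 0.87. Antigen presentation genes were called higher with 0 of 15 members over all genes and 0 adjusted over the list alone (adjusted p = 0.00232, and adjusted p = 0.0896 with an estimated correlation). Adhesion and surface receptor genes were called higher with CD83 and ICAM1 among 23 members and 2 adjusted over the list alone (adjusted p = 0.00524, and adjusted p = 0.169 with an estimated correlation). Notch, TGF-beta and BMP genes were called lower with ID1, ID2, ID3 and TGIF1 among 22 members and 6 adjusted over the list alone (adjusted p = 0.0232, and adjusted p = 0.073 with an estimated correlation).

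In 30 of the 99 genes both groups lay below the background bound, with log2 differences of up to 0.38 in size. Among them were AURKA, and ABCG2, EGR1 and TGIF1, which lay below it in every group. The count was 35 and 40 without control replicate 1 or 2, 36 and 39 without combined-treatment replicate 1 or 3, 58 without TNFa replicate 3 and 152 without estradiol replicate 3. The excess of rises turned into one of falls without control replicate 3, with 46 higher and 86 lower, and with array weights, with 243 higher and 388 lower.

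**Figure D2:**
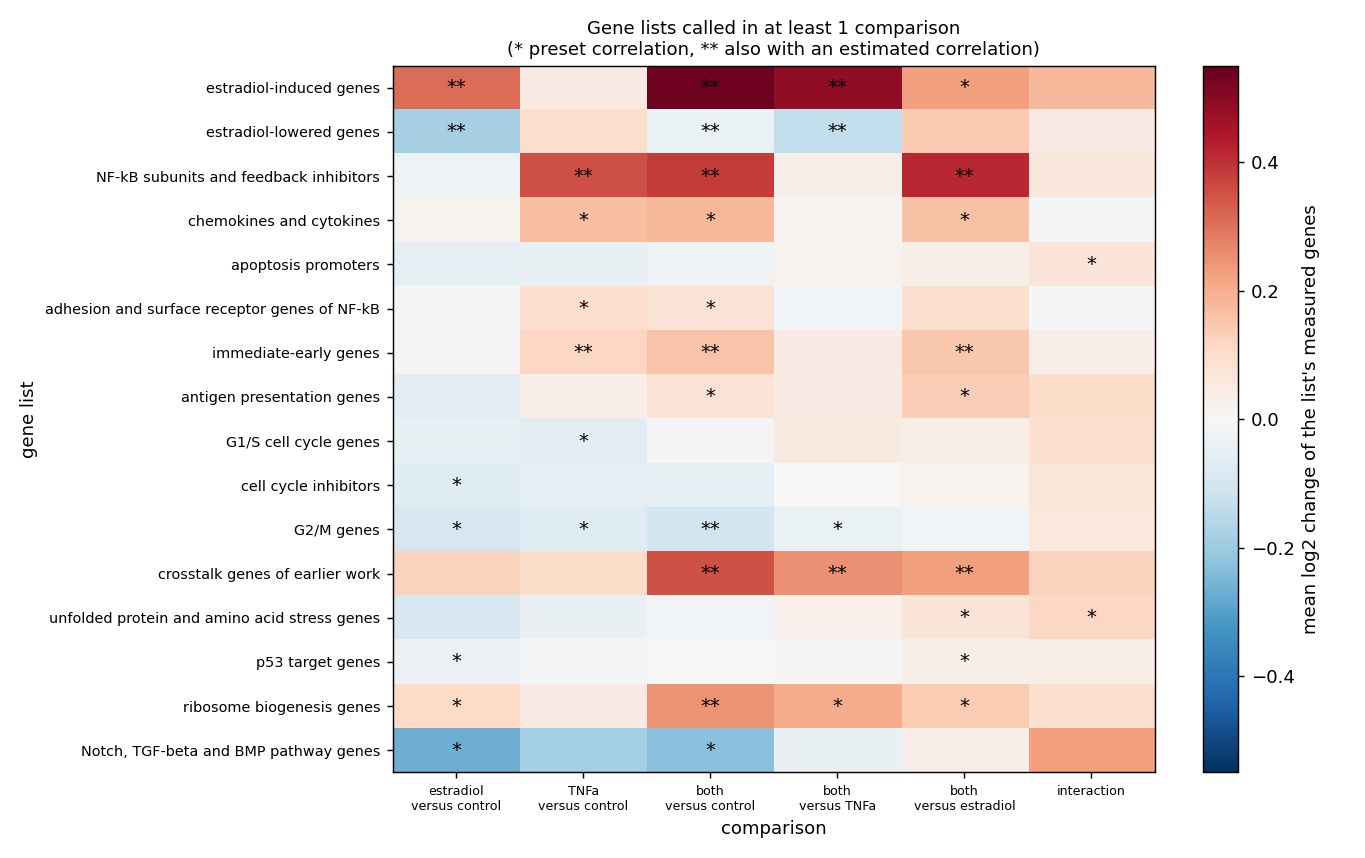
Mean log2 change of the measured genes of each gene list (rows) in each comparison (columns), as a colour scale, for the 16 lists that camera called in at least 1 comparison. Estradiol-induced genes averaged 0.31 with estradiol and 0.53 with both agents, and NF-kB genes 0.35 with TNFa and 0.38 with both.

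In cells given TNFa, adding estradiol raised estrogen-responsive genes and lowered others, among them some that TNFa had raised. TFF1 was at least 30.5-fold higher with both agents than with TNFa, by 5.08 ± 0.36 on the log2 scale (SE, n = 3), HSPB8 was 10.1-fold higher and HOXC6 at least 7.57-fold higher. CA12 rose 5.35-fold. The transcription factor gene SOX4 fell, with a change of -2.16 ± 0.28, as did RIPK2 at -1.98 ± 0.22, GATA3 at -1.90 ± 0.20 and EFNA1 at -1.87 ± 0.13. The other 4 probe sets of SOX4 had -0.69 to -0.03, with 1 of them called. A second probe set of RIPK2 had -0.04 and the 2 dimmer ones of GATA3 -0.16 and -0.18, without a call. Of the 16 genes that TNFa raised, 4 were lower with both agents than with TNFa (EFNA1, RIPK2, ATP1B1 and SLC5A6) and 0 were higher. These 16 were chosen for high values on the TNFa arrays that are used again here, which favours lower over higher. EFNA1 also fell with estradiol alone, at -1.37, and none of the 4 passed the interaction test.

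This comparison asked for the effect of estradiol in the presence of the cytokine. Limma called 36 genes, 25 higher and 11 lower. B4GALT1, NINJ1 and the ubiquitin ligase gene SIAH2 rose by 1.61, 1.60 and 1.52, NHERF1 by 1.41, the luminal keratin KRT19 by 1.24 and BLVRB by 1.17. ATP1B1 fell by 1.31, ENC1 by 0.70, SLC5A6 by 0.40, DRAM1 by 0.34, TGIF1 by 0.29 and TACC1 by 0.28. NFKBIA, which TNFa raised 13.7-fold, differed by 0.10 ± 0.21 and TNFAIP3 by -0.21 ± 0.06, with adjusted p of 1 and 0.365.

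The estradiol-induced list rose (camera adjusted p = 1.35e-24, and 0.00608 with an estimated correlation), with 9 of 50 members over all genes and 21 adjusted over the list alone. The estradiol-lowered list fell (adjusted p = 4.19e-05, and 0.0117 with an estimated correlation), with EFNA1 lower among 20 members and 4 adjusted over the list alone. The earlier crosstalk list was called higher (adjusted p = 1.41e-05, and 0.0117 with an estimated correlation), with ABCG2 higher by 0.27 among 3 members and 2 adjusted over the list alone, again not independent evidence. This call was lost among genes above the background bound (adjusted p = 0.0805), while a second probe set of PTGES and 2 dimmer ones of PHLDA1 were called higher, by 0.55, 0.32 and 0.26. Ribosome biogenesis genes were called higher with 0 of 15 members over all genes and 5 adjusted over the list alone (adjusted p = 5.61e-08, and adjusted p = 0.0986 with an estimated correlation). G2/M genes were called lower with 0 of 21 members over all genes and 0 adjusted over the list alone (adjusted p = 0.00852, and adjusted p = 0.423 with an estimated correlation). That call was also lost among genes above the background bound.

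Across genes, the effect of estradiol with TNFa correlated with its effect without TNFa at r = 0.366, and genes are not independent replicates. Simulated groups without effects had a mean of 0.024, but their spread was not kept, so that mean is no yardstick for 0.366. The correlation was 0.540 and 0.171 without estradiol replicate 2 or 3, 0.202 without combined-treatment replicate 2, and 0.164 with array weights. Of the 27 genes that estradiol called without TNFa, 26 had the same sign with it and 8 were called the same way, with a median ratio of the log2 effects of 0.522. Of the 36 genes called with TNFa present, the reverse ratio was 0.511, so the shrinkage comes with the choice of called genes and is no measure of a weaker effect. The count of 36 was 12, 19 and 14 without TNFa replicate 1, 2 or 3, 12 and 14 without combined-treatment replicate 1 or 3, 19 and 23 without control replicate 1 or 2, and 21 and 60 without estradiol replicate 1 or 3.

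**Figure D3:**
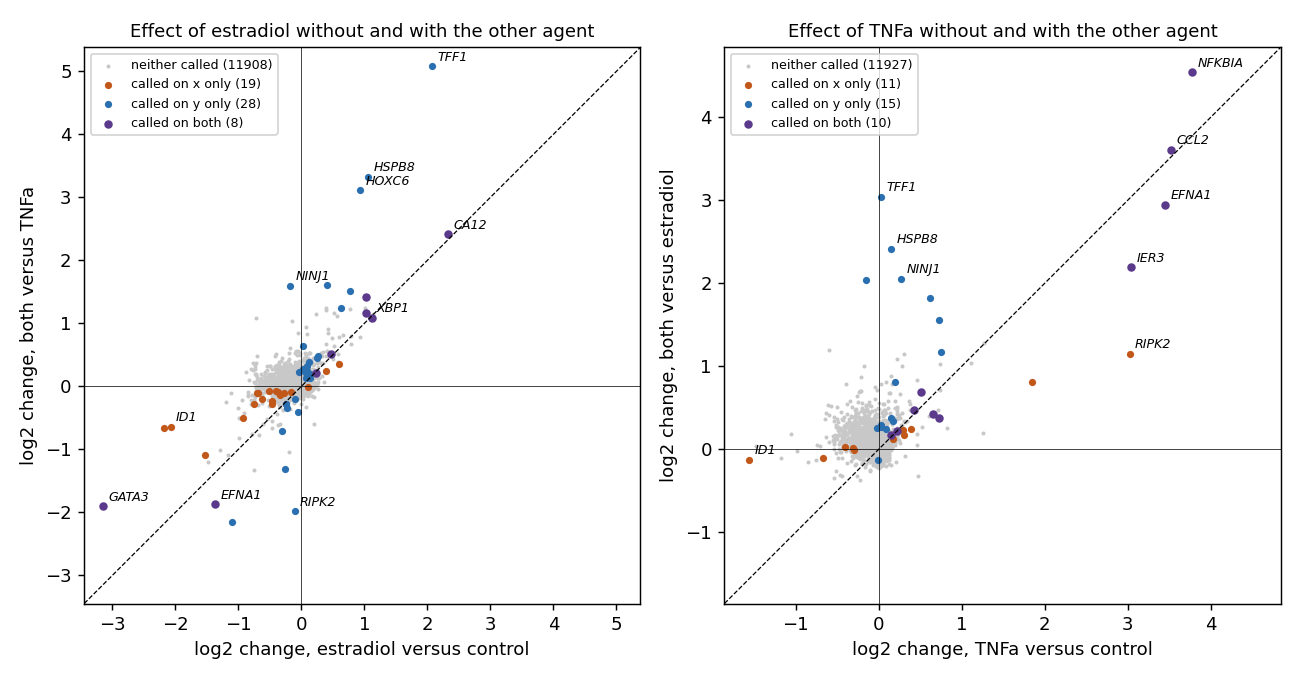
Log2 effect of each agent on 11963 genes without the other agent (horizontal) and with it (vertical), estradiol on the left and TNFa on the right, with the line of equality dashed and genes coloured by limma's call. TFF1 lies at 2.07 and 5.08 for estradiol, and NFKBIA at 3.78 and 4.54 for TNFa.

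In cells given estradiol, adding TNFa raised NF-kB genes and 4 of the 50 estradiol-induced genes of the list, but 0 of the 9 genes that estradiol had raised alone. These 9 were chosen for high values on the estradiol arrays that are used again here, which works against a further rise. NFKBIA was 23.3-fold higher with both agents than with estradiol, by 4.54 ± 0.21 on the log2 scale (SE, n = 3), and CCL2 at least 10.9-fold higher. TFF1 rose 8.24-fold and HSPB8 5.34-fold, although neither passed the test with TNFa alone, where their differences from control were 0.03 and 0.15. EFNA1 rose by 2.95, IER3 by 2.19, NINJ1 by 2.05, HOXC6 by 2.04, B4GALT1 by 1.82 and IL17RB by 1.55.

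This comparison asked for the effect of TNFa in the presence of estradiol. Limma called 25 genes, 24 higher and 1 lower, VGLL1, which fell by 0.13 below the background bound. All 16 genes that TNFa raised alone had positive differences here. The NF-kB list rose (camera adjusted p = 5.18e-08, and 0.00735 with an estimated correlation), with NFKBIA and TNFAIP3 higher over all genes among 16 members and 7 adjusted over the list alone. Immediate-early genes were called higher (adjusted p = 5.83e-05, and 0.0132 with an estimated correlation) with EGR1 and IER3 among 33 members, and 5 higher and 1 lower adjusted over the list alone. The earlier crosstalk list was called higher (adjusted p = 0.000241, and 0.0261 with an estimated correlation), with ABCG2 higher among 3 members and 2 adjusted over the list alone, not as independent evidence. This call was lost with dim genes left out and among genes above the background bound (adjusted p up to 0.174), while a second probe set of PTGES and 2 dimmer ones of PHLDA1 were called higher, by 0.61, 0.44 and 0.26. Another 6 lists were called higher, and these calls were lost with an estimated correlation. Antigen presentation genes (adjusted p = 0.000324, and adjusted p = 0.0864 with an estimated correlation) had 0 of 15 members higher over all genes and 5 adjusted over the list alone, and ribosome biogenesis genes (adjusted p = 0.000815, and adjusted p = 0.313 with an estimated correlation) 0 of 15 and 0. Chemokines and cytokines (adjusted p = 0.00807, and adjusted p = 0.526 with an estimated correlation) had 2 of 31 and 7, with a mean of 0.16 and a median of -0.00, and p53 target genes (adjusted p = 0.0258, and adjusted p = 0.112 with an estimated correlation) 0 of 14 and 3. Genes of the unfolded protein and amino acid stress response (adjusted p = 0.0339, and adjusted p = 0.413 with an estimated correlation) had 0 of 16 and 1, and estradiol-induced genes (adjusted p = 0.044, and adjusted p = 0.526 with an estimated correlation) 4 of 50 and 6, with 2 lower adjusted over the list alone.

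Across genes, the effect of TNFa with estradiol correlated with its effect without estradiol at r = 0.285, against a mean of 0.049 in simulated groups. It was 0.120 without control replicate 3, and 0.479 and 0.0746 without estradiol replicate 2 or 3. Without combined-treatment replicate 2 it was 0.180, and with array weights 0.0410. With weights or without estradiol replicate 3 it came close to the simulated mean, whose spread was not kept. Of the 21 genes called with TNFa alone, 19 had the same sign with estradiol and 10 were called the same way, with a median ratio of 0.652, against a reverse ratio of 0.470 over the 25 genes called with estradiol present. The count of 25 was 12 and 92 without estradiol replicate 1 or 3, and 11 and 44 without combined-treatment replicate 1 or 2. After quantile normalization 49 genes were called, 40 higher and 9 lower, and with the array span as a covariate 50, 38 higher and 12 lower. Rises were less dominant without estradiol replicate 3, with 62 higher and 30 lower, and with array weights, with 107 higher and 76 lower.

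A few genes responded to the combination differently from the sum of the 2 single effects. NINJ1 was at 5.48 in control, 5.29 with estradiol and 5.75 with TNFa but at 7.35 with both, an excess over the sum of 1.78 ± 0.09 on the log2 scale (SE, n = 3 per group), or 3.44-fold. HOXC6 went from 4.92 in control to 5.85 with estradiol, 4.77 with TNFa and 7.89 with both, an excess of 2.19 ± 0.25. Because control and TNFa lay below the background bound for HOXC6, this size is compressed. It was 3.83 after a background level of 4.62 was subtracted, a value without SE. That value depends on the level chosen, since the TNFa mean lay close to it. For NINJ1 the same subtraction gave 2.69. ID1 fell with each agent, with changes of -2.08 and -1.56, and of -2.20 with both, so that its interaction was positive at 1.43 ± 0.18. For ID1 the sum of the single effects lay below the lowest value of the table, 4.16.

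This comparison asked whether the effects of the 2 agents add on the log2 scale. Limma called 3 genes for the interaction, NINJ1 (adjusted p = 3.65e-05), HOXC6 (adjusted p = 0.0319) and ID1 (adjusted p = 0.0481), all positive. The 7 genes with the next smallest p-values did not pass. TFF1 had an interaction of 3.01 ± 0.51 (adjusted p = 0.245), HSPB8 of 2.27 ± 0.34 (adjusted p = 0.135) and CD83 of 0.27 ± 0.04 (adjusted p = 0.107). RIPK2 had -1.87 ± 0.31 (adjusted p = 0.245), and BIK, FBN2 and RPL27A had 0.44, 0.29 and 0.27. ABCG2, PTGES and PHLDA1 had interactions of 0.24, 0.22 and -0.08, with adjusted p of 0.774, 0.774 and 0.872. The 4 dimmer probe sets of PHLDA1 had positive interactions of 0.02 to 0.26, without a call. In 9 genes the combination was called higher than control, estradiol and TNFa alike, and 2 of them passed the interaction test. Besides the genes already named these 9 held B4GALT1, ABCG2, HOXC11 and PNO1, and the last 2 were chosen after their values were seen. Apoptosis promoters (adjusted p = 0.0435, and adjusted p = 0.384 with an estimated correlation) and unfolded protein and amino acid stress genes (adjusted p = 0.0435, and adjusted p = 0.443 with an estimated correlation) were called positive, with 0 of 14 and 0 of 16 members passing over all genes and 1 and 0 adjusted over the list alone.

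The count of 3 was 1 without control replicate 1, TNFa replicate 2 or 3, or combined-treatment replicate 1 or 3, 7 without estradiol replicate 3 and 10 without control replicate 3, and NINJ1 was called in every one of the 22 alternatives run. After quantile normalization 8 genes were called, 6 positive and 2 negative, and with the array span as a covariate 10, 6 positive and 4 negative.

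Between the 2 single treatments, 5 genes were called lower with each agent than in control: ID1, ABCC5, BIK, FOXA1 and FBN2. They were all of the genes that TNFa lowered, and all 5 were also lower with both agents, with changes of -2.20, -0.79, -0.48, -0.39 and -0.38. They are named because there were 5, after their values were seen. EFNA1 was the 1 gene called in opposite directions, and 0 genes were higher with each. Independent lists of these sizes would share 0.0075 lower and 0.012 higher genes, and 100 simulated sets of unchanged groups against shared controls shared a mean of 0, but none of these sets called 5 genes for each agent, so an overlap of 5 could not arise in them. Across genes the effects correlated at r = 0.396, against a mean of 0.475 in the simulation, with a covariance of 0.00546 against a mean of 0.00225. The spread of these simulated values was not kept. Part of any excess may come from the shared controls, which were too few to split. The overlap of 5 was 1, 2 and 22 without control replicate 1, 2 or 3, 1, 1 and 2 without TNFa replicate 1, 2 or 3, and 3 without any one combined-treatment replicate. All genes in these overlaps were lower. The absence of shared rises did not hold in every alternative. Quantile normalization gave 5 genes higher and 8 lower with each agent, the array span as a covariate 13 and 14, and array weights 9 and 305.

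In none of the 6 comparisons did camera call 12 of the 28 lists. Their smallest adjusted p-values were 0.0693 for interferon-response genes, 0.083 for apoptosis inhibitors and survival genes, 0.0838 for reference housekeeping genes and 0.101 for cholesterol synthesis genes. For luminal epithelial markers, the receptor and its cofactors, and hypoxia genes they were 0.108, 0.127 and 0.129. Fibroblast, leukocyte, endothelial and basal epithelial markers had 0.228, 0.229, 0.232 and 0.557, and heat shock genes 0.419.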

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

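The tests of the array span, of same-numbered arrays, of shared or differently handled controls and of a signal floor were chosen after the results they address were seen. The tests of unequal quantiles, of a deviating control array and of other splits of the arrays were written down earlier.

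Interactions were singled out because the effect of an agent differed with the other agent present: NINJ1 at 1.78, HOXC6 at 2.19, ID1 at 1.43, apoptosis promoters at a mean of 0.0725 and unfolded protein and amino acid stress genes at a mean of 0.113. The means of these lists are small, and with an estimated correlation neither list was called. Probe sets that lack a single gene name were tested in a fit of all 22215 probe sets, with the adjustment over these, because no gene result covers them. Limma called 3 for estradiol against control, 1 for TNFa against control, 10 for both against control, 2 for both against TNFa, 2 for both against estradiol and 1 for the interaction. The last has no gene name in the annotation used here and was also the 1 called for TNFa: it averaged 4.64 in control, 4.62 with estradiol, 5.27 with TNFa and 4.67 with both. Its rise with TNFa was 0.63 ± 0.02 (adjusted p = 7.6e-07) and its interaction -0.58 ± 0.03 (adjusted p = 5.52e-05), so that the rise was absent with estradiol.

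The arrays of a group spread along 1 shared axis, which held 69.2% of the variance that remained after the group means. The position of the 12 arrays on it followed their signal span with r = 0.994 (Spearman rho 0.986, permutation p = 1e-05 for each, the smallest that 100000 resamples give), and with r = 0.991 without the 2 farthest arrays, although span and axis come from the same values. Same-numbered arrays moved together in 7 of 18 pairs, which argues against a preparation shared by replicate number as the source of this axis. Because the axis dominates these correlations, a smaller effect shared by replicate number could not be seen. After quantile normalization the first axis held 53.9% of the remaining variance and 0.515 of its own earlier variance, so unequal quantiles may account for part of it but not for the whole. The tables cannot tell whether the span differs through labelling, hybridization or the cells.

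Splits of the 6 arrays of a comparison number 10, too few for a share under 0.05, so they can neither exclude nor establish a chance result. For estradiol against control 2 of the 10 splits called as many genes as the real one: the real split called 27 and the highest other 1740. That split set control 1, control 2 and estradiol 3 against control 3, estradiol 1 and estradiol 2, the wide against the narrow arrays, and so points to a structure of the samples. For both against estradiol 2 splits reached the real 25, the highest other calling 523 with estradiol 1, estradiol 2 and combined-treatment 2 against the other 3, again the narrow arrays. For TNFa against control only the real split, 1 of 10, reached its 21 (highest other 1), for both against control 1 of 10 reached 99 (highest other 0), and for both against TNFa 1 of 10 reached 36 (highest other 0). For the interaction 1 of 100 regroupings of the residuals, the real one, reached 3 genes, and the highest other called 0.

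The 5 genes that were lower in all 3 treated groups than in control may mark a common response or a property of the control arrays. A chance deviation of shared control arrays stays open: it gave an overlap this large in 0 of 100 simulated sets, but 0 of these sets called 5 genes for each agent, so the simulation could not decide. Leaving 1 control array out kept each change of the 5 genes at a ratio of at least 0.825. These genes were chosen by calls against all 3 control arrays, which made a large loss unlikely beforehand, so the ratio cannot exclude a deviating array. The size of the overlap did depend on single control arrays, at 1, 2 and 22 genes without control replicate 1, 2 or 3. A different handling of the control cells stays open as well: 0 genes were higher in all 3 treated groups, and the design has no control handled as the treated cells.

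The positive interactions of NINJ1 and HOXC6 could come from a signal floor or from the unequal span. The lower of their 2 additive expectations was 5.57, above the background bound of 4.97, and with the span as a covariate the lower ratio of the interaction to its main value was 0.879, so neither argues for an artifact. For ID1 the additive expectation was 3.16, below the lowest value of the table, 4.16, so a signal floor would produce its positive interaction by itself. Whether the NINJ1 and HOXC6 transcripts rise through synthesis or stability stays open.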

How the results depend on the processing

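Where the text below gives a moved count, the cause was not tested. The array span as a covariate, the restriction to genes above background and the fit without the 2 narrowest arrays were added after the data were seen. Both of these narrowest arrays are estradiol arrays, so that fit measures estradiol from 1 array, with the spread supplied by the other groups, and its values cannot show that the span is the reason for a move or a reversal. A choice of added constant was not run, since the values are log2. No named gene call changed its sign under any alternative, and the median change of all genes stayed under 0.01 in size with quantile normalization, median scaling and the array span as covariate. Signal over background sets a limit that no alternative lifts: changes near the background are compressed.

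For estradiol against control 27 genes became 96 (37 higher, 59 lower) with quantile normalization, 1 with 2 groups only, 57 with trend and robust moderation, 2327 (951 higher, 1376 lower) with array weights, 15 with the replicate number as a block, 171 with the array span as covariate and 46 without the 2 narrowest arrays, and 9 to 304 without 1 array. For TNFa against control 21 became 42, 13, 38, 483, 12 and 102 in the first 6 of these, and 10 to 34 without 1 array. For both against control 99 became 213 with quantile normalization, 49 with 2 groups, 631 with weights, 50 with the block, 511 with the span, 151 without the narrowest arrays and 35 to 152 without 1 array. For both against TNFa 36 became 88 with quantile normalization, 57 with trend, 167 with weights, 23 with the block, 164 with the span, 63 without the narrowest arrays and 12 to 60 without 1 array. For both against estradiol 25 became 49 with quantile normalization, 6 with 2 groups, 183 with weights, 50 with the span and 11 to 92 without 1 array. The interaction's 3 became 8 with quantile normalization, 6 with trend, 14 with weights, 10 with the span and 1 to 10 without 1 array. The weights gave control replicate 1 3.80 and estradiol replicate 2 0.265.

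The correlation of the estradiol effects, 0.366, became 0.522 with quantile normalization, 0.164 with weights, 0.675 with the span, 0.716 without the narrowest arrays and 0.171 to 0.540 without 1 array. For TNFa 0.285 became 0.468, 0.0410, 0.625 and 0.693 in these, 0.417 above background and 0.0746 to 0.479 without 1 array. The overlap of 5, all lower, became 13 with quantile normalization, with 5 higher and 8 lower. With weights it was 314, 9 higher and 305 lower, and with the span 27, 13 higher and 14 lower. It was 11 with trend, 2 with the block, 3 above background and 1 to 22 without 1 array, all lower. Heat shock genes reversed the sign of their mean, to 0.128 with the span and 0.165 without the narrowest arrays for estradiol against control, to -0.133 and -0.112 for the interaction, and to -0.135 without the narrowest arrays for both against estradiol, where ribosome biogenesis genes went to -0.0053. None of the reversed heat shock means had been called in the main fit. With the span as a covariate, however, the reversed means were called in the new direction. Calls of the fit without the narrowest arrays are left out here because it rests on 1 estradiol array, so no contrast between the 2 settings is meant.

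The replicate number of the titles is not said to mark a shared day: residuals of same-numbered arrays correlated between -0.794 and 0.764. Of the named calls, 1 of 23 for estradiol against control, EFNA1, was kept under every alternative, as were 7 of 20 for TNFa, 19 of 46 for both against control, 10 of 24 for both against TNFa, 4 of 17 for both against estradiol and 1 of 3 for the interaction, NINJ1.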

Other observations

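Genes of the HOXC cluster, which encode homeobox transcription factors of the body axis, rose with the combination. Of 7 measured HOXC genes 5 were higher with both agents than in control: HOXC6 by 2.97 ± 0.18 (SE, n = 3), HOXC11 by 0.84 ± 0.10, HOXC4 by 0.52 ± 0.07, HOXC10 by 0.22 ± 0.04 and HOXC5 by 0.15 ± 0.02. HOXC13 and HOXC8 differed by 0.18 and 0.04 (adjusted p = 0.11 and 0.892). Of 17 measured genes of the HOXA, HOXB and HOXD clusters 0 were higher. The cluster was chosen after its values were seen, so a Fisher test of it against the other clusters (p = 0.000494) is no evidence of a difference. HOXC5 and HOXC10 lay below the background bound in every group.

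With estradiol alone HOXC4 rose by 0.47 (adjusted p = 0.0266), while HOXC6 differed by 0.93 (adjusted p = 0.0971) and HOXC11 by 0.03. With TNFa alone HOXC6 differed by -0.15 and HOXC11 by 0.20 (adjusted p = 0.996 for each). A rise of the whole chromosome region would include the neighbours of the cluster. Among the 25 genes on each side 31 were measured, 9 of them above background. Of these 31 genes 0 were called higher, and their median change was -0.02. HOXC4 averaged 5.33 with estradiol alone and 5.38 with both agents, and HOXC5 4.80 and 4.82, so TNFa added little to either. HOXC6 and HOXC11 were highest with both agents. A shared enhancer that needs both estrogen receptor alpha and NF-kB could explain their joint rise, which the values do not test. Chromatin immunoprecipitation of the receptor and of the NF-kB subunit RELA across the cluster with each agent and both would test it, with nascent transcript counts of HOXC4, HOXC6 and HOXC11.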
